A study of Mus musculus with 24 samples.

How the data were processed

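Gene expression was measured in the hippocampus of male mice with 24 Affymetrix Mouse Gene 1.0 ST arrays, 1 column per array and 6 arrays in each of 4 groups. The groups cross genotype (wild type, WT, against a FoxO6 mutant) with state (basal, or taken after an object learning task). The deposited table holds log2 values that the authors made with RMA, which corrects the background, sets the quantiles of the arrays equal and summarises the probes of a transcript cluster. The version of RMA and the chip definition are not given in the sources used here. The range of the values and the medians, between 6.16 and 6.30, were checked in every column before use, and the table had 0 missing values. The values were not transformed further.

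The table has 35511 probes (transcript clusters). By the platform annotation, dated 2016, 21789 probes carry 1 gene symbol, 1621 carry several and 12101 carry none. Gene comparisons used the probes with 1 symbol, and for the 999 genes with more than 1 such probe the probe with the highest mean over all 24 arrays, which left 19938 genes. No filter on dim genes was applied. Of the probes with 1 symbol, 21698 had an Entrez identifier in the reference used here, and 0 symbols needed an update. Probes without a single gene were left out of the gene comparisons and tested only as described in the closing section.

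Comparisons were made in R 4.3.3 with limma 3.58.1. One linear model gave each group its own mean over all 24 arrays (20 residual degrees of freedom), and eBayes with a mean-variance trend moderated the spread of each gene, for 29.0 degrees of freedom in all. The 6 comparisons were mutant minus WT at basal, mutant minus WT after learning, their average over both states, learning minus basal in WT, learning minus basal in the mutant, and the interaction, which is the genotype difference after learning minus that at basal. P values are two-sided and were adjusted by Benjamini and Hochberg over all genes of a comparison. A gene was called at an adjusted p under 0.05. Every adjusted p of a gene comes from limma, and standard errors (SE) and 95% confidence intervals use its moderated spread. Group values are mean ± SD with n = 6. The levels of Foxo6 and the other FoxO genes were also compared by an exact two-sided permutation test over all 924 assignments of 12 arrays to groups of 6.

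Lists of genes, 31 with 818 members of which 69 were not measured, were written before the data were examined, as were the comparisons, the tests and the rule for named genes. They cover activity-induced genes, stress responses, synapses, ion channels, axon guidance, signalling, metabolism, ribosomes, hippocampal and other brain cell types, neighbouring tissue and blood. Each list was tested with camera in limma, which asks whether its genes differ more in 1 direction than other genes, with a preset correlation of 0.01 between genes, and adjusted over the 31 lists of a comparison. The test was repeated with the correlation estimated from the arrays, and the adjusted p of that test is printed beside each called list. Counts of called members are given over all genes, and adjusted over the list alone. Genes near Foxo6 were compared with all others by Fisher's exact test, two-sided, with gene positions of mouse assembly GRCm38.p6, known for 19855 genes, and a window of 20 Mb to each side. Correlations across genes describe how alike 2 sets of differences are, and genes are not independent replicates.

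The rule for named genes was as follows. Foxo6, Foxo1, Foxo3 and Foxo4 are always reported. In each comparison the 10 called genes with the largest positive and the 10 with the largest negative difference are named. From each list up to 3 called members with the smallest p per direction are named, or, with none called, the 2 members with the smallest p are given as values. In a comparison with fewer than 5 called genes, the 5 genes with the smallest p in each direction are given as values. Symbols that are only clone or model names, olfactory and vomeronasal receptors and pseudogenes were skipped among named genes but stayed in every count. For lists that were not called, the text gives counts or the range of the tests, and names members only in WT mice after learning. Genes named outside this rule are said to be chosen after their values were seen. Other probes of a named gene that disagreed in sign at an unadjusted p under 0.05 are pointed out.

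The method was tested on simulated data with the same number of arrays. In a genotype comparison it found 43.3% of genes changed by 0.25 on the log2 scale, 95.5% of those changed by 0.5 and 98.5% of those changed by 1. For the interaction it found 22.4%, 73.1% and 95.5% in the same order. For each size 66 or 67 genes were changed at once, and the adjustment is stricter where fewer genes change. These shares therefore need not hold for a comparison with few or 0 called genes. The method called 10 genes that had not been changed in the genotype comparison and 11 in the interaction. In all 19938 genes were simulated, the changed ones included. The shifted list was called, and 0 of the others were. The simulated genes were drawn independently, without the correlation between genes that real arrays hold. The list result therefore does not show how camera treats lists of correlated genes.

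Alternatives were tried for the normalization, a filter on dim genes (25% or 50%), the probe per gene, the replicate number as a block, the variance model, array weights, the arrays in the model, a component of the residuals as a covariate, the thresholds, a fold minimum, and each array left out in turn. Others were chosen after seeing the data: genes on the chromosome of Foxo6 left out, a choroid plexus score as a covariate, the least typical array of each group left out, and the list tests without genes near Foxo6. In 100 splits of the arrays per comparison, the real one included, genes were counted in the same way. The replicate numbers did not pair the arrays of different groups, as the closing section shows, so no paired test was used. The image files of the arrays were not used here, and neither scan dates nor probe sequences were, so processing batches could not be looked for. For arrays, their number limits the precision of each value.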

Results

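The data are 24 array measurements of RNA from the hippocampus of male mice aged 8 to 9 weeks on a mixed C57BL/6J-129sv background. FoxO6 is a forkhead transcription factor of the FoxO family, and the mutants are labelled as homozygous. The mice were either taken from single housing of at least 3 days (basal) or 60 min after a learning task, in which they explored a pair of identical objects for 10 min in an arena they had met empty for 10 min a day (24 h) before. WT basal, mutant basal, WT learning and mutant learning groups had 6 arrays each. The comparisons ask what loss of FoxO6 changes in the hippocampus in each state, what changes after the task, and whether that change depends on FoxO6. Within groups, pairs of arrays correlated across genes at 0.991 to 0.997. The first principal component held 46.6% of the variance and separated all learning arrays (lowest 11.98) from all basal arrays (highest −14.27). The number of arrays limits the precision. The labels call the arrays of a group biological replicates but do not say whether each came from a separate animal, so the p values measure the spread between these samples.

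Foxo6 RNA was lower in the mutant in both states, measured by 1 probe. At basal it was 6.30 ± 0.16 (log2, SD, n = 6, range 6.18 to 6.59) in the mutant against 7.03 ± 0.20 (6.78 to 7.30) in WT, a difference of −0.73 (95% interval −0.91 to −0.54) that left 60.4% of the WT signal. After learning it was 6.24 ± 0.15 (5.98 to 6.38) against 6.87 ± 0.15 (6.62 to 7.04), a difference of −0.63 (−0.81 to −0.44), or 64.7%. The exact permutation test gave p = 0.00216 in each state, the smallest that 924 assignments allow. The adjusted p from limma was 0.000128 and 0.000833. Where the probe lies relative to the changed part of the gene is not given in the sources used here. The mutant means lay near the medians of the arrays (6.16 to 6.30), and signal over background was not used. How much Foxo6 RNA the remaining signal stands for was therefore not tested. The other FoxO genes were not called by limma between genotypes: the differences at basal and after learning were 0.11 and −0.07 for Foxo1, 0.04 and −0.07 for Foxo3 and −0.04 and 0.00 for Foxo4. The exact permutation test, without adjustment, gave p = 0.0368 for Foxo1 at basal and 0.275 to 0.994 for the rest. After learning, Foxo1 fell by 0.24 in WT (adjusted p = 0.000518) and by 0.42 in the mutant (adjusted p = 1.74e-07). Foxo4 fell by 0.17 in WT (adjusted p = 0.0258), a call that ended without WT basal array 4 or 5 or WT learning array 3 or 4 (up to 0.0826). Foxo4 differed by −0.13 in the mutant (adjusted p = 0.0952). The exact permutation test of Foxo4 between learning and basal, without adjustment, gave p = 0.0238 in each genotype. Foxo3 differed by 0.05 in WT and −0.05 in the mutant, and Foxo6 itself by −0.16 (adjusted p = 0.169) and −0.06 (adjusted p = 0.652).

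**Figure D1:**
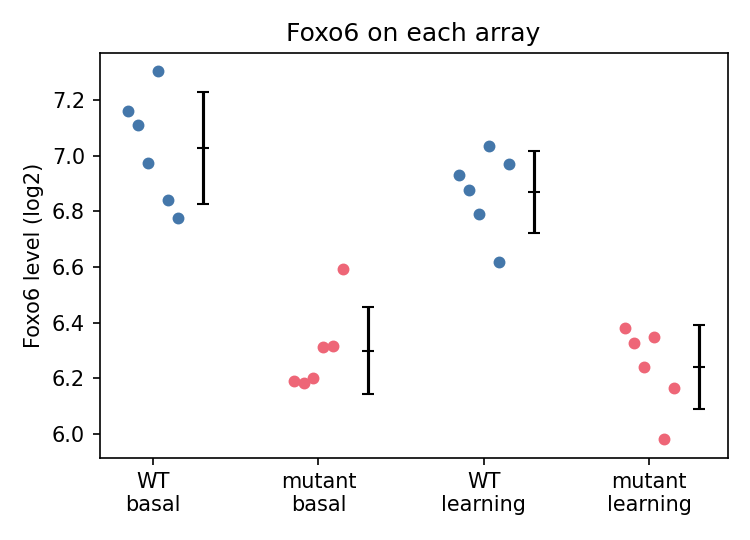
Foxo6 level (log2) of each array by group. Points are arrays, and black bars give the mean and SD of 6 arrays; the highest mutant array (6.59) lies below the lowest WT array (6.62).

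In the basal hippocampus, loss of FoxO6 went with different RNA levels of a few genes, some of which lie near Foxo6. The largest difference among called genes was in Ndufs5, a subunit of mitochondrial complex I, at 8.17 ± 0.22 in the mutant against 9.04 ± 0.26 in WT (−0.87, SE 0.114, 0.547-fold, adjusted p = 0.000134). Grp, which encodes gastrin-releasing peptide, was lower by −0.53 (SE 0.0672, 0.695-fold, adjusted p = 0.000128). Crym, a thyroid hormone binding protein, was lower by −0.34 (0.788-fold, adjusted p = 0.0014) and Fibcd1, a transmembrane receptor found in CA1 pyramidal cells, also by −0.34 (0.792-fold, adjusted p = 0.00563). Among genes higher in the mutant were Kcnv1, a modulatory potassium channel subunit (0.29, 1.23-fold, adjusted p = 0.0151), and the cell surface proteins Itga4, an integrin (0.37, adjusted p = 0.0295), and Alcam, an adhesion molecule (0.20, adjusted p = 0.0151). In all, 20 genes were called, 9 higher and 11 lower in the mutant, and 898 had an unadjusted p under 0.05 where chance gives 996.9. The other higher genes were the receptor Gpr165 (0.41, adjusted p = 0.033), the isomerase Hyi (0.41, adjusted p = 0.0151), the actin regulator Phactr4 (0.34, adjusted p = 0.0284), Itgbl1 (0.33, adjusted p = 0.0382), the lysosomal thioesterase Ppt1 (0.24, adjusted p = 0.0151) and Clic4 (0.24, adjusted p = 0.0371). The other lower genes were Foxo6, the lysosomal membrane protein Laptm5 (−0.50, adjusted p = 0.0163), the transcription cofactor Vgll3 (−0.39, adjusted p = 0.0445), the ciliary rootlet gene Crocc (−0.35, adjusted p = 0.0445), Thrap3 (−0.25, adjusted p = 0.0191), Klhl2 (−0.20, adjusted p = 0.0229) and Stxbp6 (−0.19, adjusted p = 0.0371). Foxo6, Ndufs5, Grp, Crym and Fibcd1, 5 of the 20, were called whichever array was left out. Of the rest, Hyi lost its call only without WT basal array 4 (adjusted p = 0.0507), Alcam without WT basal array 5 or mutant basal array 2 (up to 0.0531), Ppt1 without WT basal array 2 or mutant basal array 2 (up to 0.0623) and Laptm5 without mutant basal array 2 or 6 (up to 0.0529). Kcnv1 and Thrap3 kept it in 7 of 12 such runs, Klhl2 in 5, Gpr165, Itga4 and Phactr4 in 4, Crocc and Stxbp6 in 3, Itgbl1 and Clic4 in 2 and Vgll3 in 1 (up to 0.213). The count fell to 9, 10, 11 and 10 without WT basal array 2, 3, 4 and 5 and to 6, 12 and 9 without mutant basal array 2, 3 and 6. It was 6 without the genes within 20 Mb of Foxo6, 10 with each array centred on its median, 11 with only the basal arrays in the model and 51 with array weights.

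Cell type markers also differed at basal. Of 12 markers of dentate gyrus granule cells, 10 were lower in the mutant (median −0.10, adjusted p = 1.08e-07 for the list; adjusted p = 0.0598 with an estimated correlation). The mean of the markers lay below the WT mean in 6 of 6 mutant arrays. Stxbp6 was the member called over all genes, and 4 were called lower when adjusted over the list alone. Of 18 interneuron markers, 17 were higher (median 0.11, adjusted p = 5.37e-06; adjusted p = 0.0598 with an estimated correlation), with the mean above that of WT in 6 of 6 mutant arrays. Of these markers 0 were called (Gad2, the GABA-synthesising enzyme, 0.13, adjusted p = 0.777; Erbb4 0.19, adjusted p = 0.802), also when adjusted over the list alone. Beside these lists, all 17 choroid plexus markers were higher in the mutant arrays (median 0.17, adjusted p = 2.41e-05; adjusted p = 0.514 with an estimated correlation). None of the 17 was called, and the most abundant, Ttr, stood at 11.53 ± 0.36 in the mutant and 10.53 ± 1.49 in WT (difference 0.99, SE 0.471) with Cldn1 at a difference of 0.31 (adjusted p = 0.794). The WT arrays stood apart: Ttr was 11.65, 12.11 and 11.81 in WT basal arrays 1, 2 and 3 and 8.80, 9.64 and 9.17 in arrays 4, 5 and 6, against 11.01 to 11.99 in the mutant. The mean of the choroid plexus markers parted them the same way. Potassium channel genes were higher (41 of 51, median 0.06, adjusted p = 0.000105; adjusted p = 0.194 with an estimated correlation), with Kcnv1 called over all genes and 4 called higher when adjusted over the list alone. Genes of glutamate receptors and the postsynaptic density were higher (39 of 47, median 0.04, adjusted p = 0.0045; adjusted p = 0.292 with an estimated correlation; 0 called either way; Grik4 0.18, Homer2 0.25). So were neuropeptide and granin genes (18 of 23, median 0.06, adjusted p = 0.0055; adjusted p = 0.194 with an estimated correlation; 0 called and 1 when adjusted over the list alone; Penk 0.24, adjusted p = 0.334). Neocortical layer markers were higher too (12 of 14, median 0.06, adjusted p = 0.0137; adjusted p = 0.194 with an estimated correlation; 0 called and 1 when adjusted over the list alone; Lamp5 0.18, adjusted p = 0.229). Oxidative phosphorylation genes were higher in 57 of 72 (median 0.03, adjusted p = 0.042; adjusted p = 0.712 with an estimated correlation), but this test turned to the other direction without WT basal array 6 (median 0.00022) and without the least typical array of each group (0.0065). Their called member, Ndufs5, was lower, over all genes and when adjusted over the list alone. The other 23 lists were not called (adjusted p 0.0952 to 0.843), and among them the heat shock list had a median of 0.0091 while its test pointed down. Clock genes (median −0.0023), oligodendrocyte markers (−0.0026) and thalamic markers (−0.0028) had means above 0. Without mutant basal array 1 or 2 the glutamate receptor, neuropeptide, oxidative phosphorylation and neocortical lists were no longer called (4 lists left each time). Those for neuropeptides and oxidative phosphorylation also ended without WT basal array 6, oxidative phosphorylation without WT basal array 4 or mutant basal array 3 or 5, and neocortical markers without WT basal array 1 (adjusted p up to 0.502). Without WT basal array 3, 14 lists were called.

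After the learning task, loss of FoxO6 went with lower Grp, Crym and Fibcd1 again, and with lower Hmgb2, a chromatin protein. Grp was 8.70 ± 0.14 in the mutant and 9.25 ± 0.11 in WT (−0.55, SE 0.0672, 0.684-fold, adjusted p = 5.49e-05). Fibcd1 was lower by −0.35 (0.785-fold, adjusted p = 0.00226), Crym by −0.29 (0.82-fold, adjusted p = 0.0141) and Hmgb2 by −0.37 (0.775-fold, adjusted p = 0.0245). Alcam was again higher (0.18, adjusted p = 0.035), and so was the sulfotransferase Chst8 (0.29, adjusted p = 0.0245). The largest difference among called genes was again in Ndufs5, at 8.53 ± 0.22 against 9.62 ± 0.21 (−1.09, SE 0.114, 0.47-fold, adjusted p = 3.68e-06). Of 15 called genes 3 were higher and 12 lower, with 1461 at an unadjusted p under 0.05 where chance gives 996.9. The rest were Hyi, higher by 0.49 (adjusted p = 0.00133), and the lower genes Foxo6, Laptm5 (−0.60, adjusted p = 0.00148), the Mediator subunit Med8 (−0.37, adjusted p = 0.044), the galactosyltransferase B3galt2 (−0.33, adjusted p = 0.0184), and Thrap3 (−0.31, adjusted p = 0.00133). Named after their values were seen, the last were Klhl2 (−0.19, adjusted p = 0.035) and Cap1 (−0.17, adjusted p = 0.0184). Alcam, Crym, Fibcd1, Foxo6, Grp, Hyi, Klhl2, Laptm5, Ndufs5 and Thrap3, 10 genes, were called in both states and in the same direction, where independent calls would share 0.00797 in the same direction. Of the 13 genes the rule names, 7 (Foxo6, Hyi, Ndufs5, Laptm5, Grp, Fibcd1 and Thrap3) were called whichever array was left out; Crym was lost without mutant learning array 3 (adjusted p = 0.0609). Hmgb2 was lost without WT learning array 1, 2 or 3 or mutant learning array 1, 3 or 4 (up to 0.0947) and B3galt2 without WT learning array 1 or 2 or mutant learning array 1, 3 or 6 (up to 0.092). Chst8 was lost without WT learning array 2, 4, 5 or 6 or mutant learning array 1 or 3 (up to 0.103), while Alcam kept its call in 3 of 12 such runs and Med8 in 2 (up to 0.14). The count of 15 fell to 8 without WT learning array 2, 8 without mutant learning array 1 and 9 without mutant learning array 3. It was 6 without the genes within 20 Mb of Foxo6, 9 with each array centred on its median, 7 with only the learning arrays in the model, 9 with array weights, 28 with every probe of the table and 58 with a residual component as a covariate. Higher genes made up 7 of 19 called after a second quantile normalization.

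After learning 3 of the lists called at basal were called, in the same direction as there. Of 12 dentate gyrus markers, 9 were lower in the mutant (median −0.11, adjusted p = 0.0102; adjusted p = 0.851 with an estimated correlation), below the WT mean in 6 of 6 mutant arrays. Of these 0 were called over all genes (C1ql2 −0.25, adjusted p = 0.499; Lct −0.19, adjusted p = 0.513) and 2 when adjusted over the list alone. Of 18 interneuron markers, 14 were higher (median 0.04, adjusted p = 0.0446; adjusted p = 0.851 with an estimated correlation) and 0 were called either way (Calb2 0.24, adjusted p = 0.427; Sst 0.18, adjusted p = 0.506). Beside them, all 17 choroid plexus markers were higher in the mutant (median 0.15, adjusted p = 0.0102; adjusted p = 0.921 with an estimated correlation), with 0 called either way (Cldn1 0.26, adjusted p = 0.6; Ecrg4 0.22, adjusted p = 0.761). None of the 3 lists kept its call through every array left out: dentate markers lost it without WT learning array 1 or mutant learning array 4 (adjusted p up to 0.0663) and choroid plexus markers without mutant learning array 4 or 6 (up to 0.246). Interneuron markers lost it without WT learning array 1, 2 or 5 or mutant learning array 2, 4, 5 or 6 (up to 0.262). The number of called lists was 0 without mutant learning array 4, 1 without WT learning array 1 or mutant learning array 6, 5 without WT learning array 6 or mutant learning array 3, and 6 without WT learning array 4. The other 28 lists were not called (adjusted p 0.107 to 0.962). Among them, CA1 markers had a median of 0.03 and a mean of −0.03, microglia markers a median of 0.01 and a mean of −0.04, and blood markers a median of 0.06 and a mean of −0.03. The heat shock list had a median of −0.01 and a mean of 0.01, and the presynaptic list (mean −0.0032) and the MEF2 list (mean −0.0010) had medians above 0. Oligodendrocyte precursor markers (mean 0.0062) had a median below 0.

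Averaged over both states, 78 genes differed between genotypes, 35 higher and 43 lower in the mutant (1766 at an unadjusted p under 0.05, where chance gives 996.9). Beside Ndufs5 (−0.98, SE 0.0806, adjusted p = 1.33e-08), Foxo6 (−0.68, adjusted p = 1.19e-07), Grp (−0.54, SE 0.0475, adjusted p = 3.95e-08), Laptm5 (−0.55, adjusted p = 7.4e-06) and Fibcd1 (−0.34, adjusted p = 5.86e-06), the lower genes included Jun, an immediate early transcription factor (−0.19, adjusted p = 0.0154). They also included the cation channel Trpc6 (−0.32, adjusted p = 0.0455), the Ras-like Rasl10a (−0.35, adjusted p = 0.00439), Cplane2, which acts in ciliogenesis (−0.38, adjusted p = 0.0355), Med8 (−0.35, adjusted p = 0.000692) and Vgll3 (−0.34, adjusted p = 0.00198). The higher genes included Htr2a, a serotonin receptor (0.24, adjusted p = 0.00978), Hcrtr1, an orexin receptor (0.25, adjusted p = 0.0355), Ret, a receptor tyrosine kinase (0.27, adjusted p = 0.0302), and Gpr165 (0.26, adjusted p = 0.0369). Scp2, a sterol carrier protein (0.50, adjusted p = 0.0015), Hyi (0.45, adjusted p = 5.86e-06), Rpph1, the RNA of ribonuclease P (0.35, adjusted p = 0.0278), Itga4 (0.33, adjusted p = 0.000818), Prag1 (0.27, adjusted p = 0.0117) and Itgbl1 (0.24, adjusted p = 0.0156) were higher too. Kcnq5, a potassium channel gene (0.13, adjusted p = 0.0467), and Igfbp4, a binding protein of insulin-like growth factors (0.15, adjusted p = 0.0355), were the other higher members of lists beside Kcnv1 (0.23, adjusted p = 0.00193). The differences of the 2 states correlated across genes at r = 0.301 (rho = 0.254). Of 27 named genes that were called, 17 were called whichever of the 24 arrays was left out. Rpph1 kept its call in 16 of 24 such runs, Ret in 14, Hcrtr1 in 12, Igfbp4 in 10, Gpr165 in 9, Cplane2 in 8, Trpc6 in 6 and Kcnq5 in 5 (adjusted p up to 0.103). The count of 78 was 36 without the genes within 20 Mb of Foxo6, 44 with each array centred on its median, 44 with the choroid plexus score as a covariate (chosen after seeing the data) and 173 with a residual component as a covariate.

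Genes near Foxo6 were called more often than others. Within 20 Mb on the same chromosome 30 of 500 genes (6%) were called over both states against 47 of 19354 elsewhere (0.243%), an odds ratio of 26.2 (95% interval 15.9 to 42.7, Fisher's exact p = 3.23e-28). Of the 30, 16 were higher and 14 lower in the mutant. Ndufs5, Hyi, Laptm5, Thrap3, Med8, Ppt1, Scp2, Cap1, Phactr4, Clic4 and Hcrtr1 lie in this window. At basal 7 of the 500 were called and after learning 6. Across genes, the differences at basal and after learning correlated at r = 0.664 (rho = 0.453) among the 500 and 0.280 (rho = 0.248) elsewhere. For learning minus basal in WT the odds ratio of the same window was 0.912 (Fisher's exact p = 0.337).

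**Figure D2:**
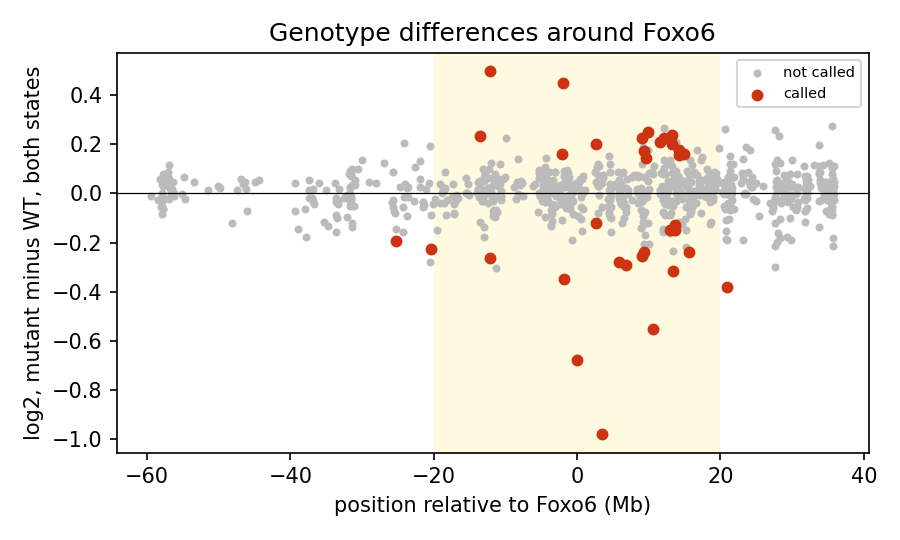
Difference between mutant and WT over both states (log2) of genes on the chromosome of Foxo6, by distance from Foxo6 (Mb). Grey points are genes that were not called and red points called genes; the shaded band reaches 20 Mb to each side and holds 30 called genes, 16 of them above 0.

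Over both states, dentate gyrus markers were lower in the mutant (10 of 12, median −0.12, adjusted p = 1.03e-06; adjusted p = 0.0883 with an estimated correlation). Of these 3 were called: C1ql2, a secreted synaptic protein (−0.29, adjusted p = 0.0227), Prox1, the transcription factor that marks granule cells (−0.20, adjusted p = 0.0355), and Stxbp6 (−0.14, adjusted p = 0.00968). Adjusted over the list alone, 7 were called lower. C1ql2 lost its call without WT learning array 1 (adjusted p = 0.0518), and Prox1 kept its call in 10 of 24 runs without an array (up to 0.0737). Interneuron markers were higher (17 of 18, median 0.08, adjusted p = 1.41e-05; adjusted p = 0.0883 with an estimated correlation), with 0 called over all genes and 5 when adjusted over the list alone (Calb2 0.20, adjusted p = 0.143; Reln 0.17, adjusted p = 0.273). Choroid plexus markers were higher beside them in 17 of 17 (median 0.16, adjusted p = 6.04e-06; 0 called, 1 when adjusted over the list alone; adjusted p = 0.477 with an estimated correlation). FoxO target genes were lower (18 of 30, median −0.02, adjusted p = 0.0188; adjusted p = 0.443 with an estimated correlation). Of these 0 were called and 2 when adjusted over the list alone, with Txnip at −0.24 (adjusted p = 0.106) and Sesn1 at −0.14 (adjusted p = 0.172). Potassium channels were higher (34 of 51, median 0.03, adjusted p = 0.0188; adjusted p = 0.527 with an estimated correlation; 2 called, also when adjusted over the list alone). Neuropeptides (17 of 23, median 0.06, adjusted p = 0.0112; adjusted p = 0.359 with an estimated correlation; 0 called, 3 when adjusted over the list alone) were too. So were oxidative phosphorylation genes (56 of 72, median 0.03, adjusted p = 0.0188; adjusted p = 0.837 with an estimated correlation; Ndufs5 called lower, also when adjusted over the list alone). Neocortical markers were higher as well (12 of 14, median 0.03, adjusted p = 0.0386; adjusted p = 0.443 with an estimated correlation; 0 called, 2 when adjusted over the list alone). Interneuron, neuropeptide, dentate and choroid plexus lists, 4 of the 8, were called whichever array was left out. FoxO targets lost the call without WT basal array 4 (adjusted p = 0.051), and 5 lists were called without WT learning array 1 or mutant learning array 5 or 6. Potassium channels lost it without WT basal array 1, mutant basal array 2, WT learning array 1 or mutant learning array 2, 5 or 6 (up to 0.131), oxidative phosphorylation genes kept it in 17 of 24 such runs (up to 0.505) and neocortical markers in 15 (up to 0.146). The other 23 lists were not called (adjusted p 0.102 to 0.970). Among them, median and mean differed in sign for immediate early genes (−0.0057 and 0.0009), heat shock genes, GABA-A receptor subunits, microglia, endothelial and meningeal markers. The tests of oligodendrocyte and thalamic markers pointed down with a mean above 0.

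After the learning task the hippocampus of WT mice differed from basal in activity-induced genes, stress-responsive genes and many others. Fos, the prototype immediate early gene, rose from 6.48 ± 0.26 to 8.08 ± 0.19 (1.60, SE 0.104, 3.03-fold, adjusted p = 3.19e-13). Egr2, a zinc finger transcription factor, rose by 1.07 (SE 0.101, 2.1-fold, adjusted p = 6.29e-10), and Arc, which acts on the trafficking of AMPA receptors, by 0.87 (SE 0.0875, 1.83-fold, adjusted p = 1.84e-09). Among genes of the synapse, Syn1, a synaptic vesicle protein, fell by 0.83 (SE 0.035, 0.563-fold, adjusted p = 6.29e-17) and Shank1, a postsynaptic scaffold, also by 0.83 (SE 0.0604). In all 8636 genes were called, 43.3% of those tested, 5004 higher and 3632 lower; 626 changed at least 1.5-fold and 23 at least 2-fold. The median of all genes moved by 0.03. The other largest rises were in the mitochondrial ribosomal protein Mrpl20 (1.42, adjusted p = 3.23e-05), the ubiquitin ligase Trim13 (1.31), the succinate dehydrogenase assembly factor Sdhaf4 (1.31) and the RNA polymerase subunit Polr3e (1.27). They were followed by Imp3, of the nucleolus (1.26), Bex1 (1.14), Hint1 (1.12), Cmbl (1.11, adjusted p = 4.56e-08) and Tmem126a (1.10). The largest falls were in Dtx3 (−1.28, adjusted p = 1.37e-16), the phospholipid transfer protein Pltp (−1.15, adjusted p = 9.87e-18), Selenow (−0.97) and Prrt1, a partner of AMPA receptors (−0.94). Further falls were in Agpat1 (−0.91), the clock repressor Nr1d1 (−0.88, adjusted p = 5.16e-11), the synaptic adhesion protein Slitrk1 (−0.86), Vps37b (−0.85), Aplp1 (−0.85) and Trim8 (−0.85). The genes of these lists of largest rises and falls without a printed adjusted p had one of at most 8.95e-11. Beside these genes, receptor genes of the olfactory and vomeronasal organs, at a mean level of 4.46, were called in 319 of 1190 cases (26.8%), 318 of them higher. Their median of 0.12 in WT was 0.07 after a second quantile normalization and 0.16 with each array centred on its median. The labels give no batch, and basal and learning arrays share no group, so a difference in processing between them cannot be told apart from the task. The split of the called genes depended on the scaling: 4447 higher and 3789 lower after a second quantile normalization, and 5825 and 2969 with each array centred on its median. At a minimum of 1.2-fold the count was 4979.

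Immediate early transcription factor genes rose in WT after learning (median 0.39, adjusted p = 0.000185; adjusted p = 0.117 with an estimated correlation). Of 24 members 15 rose, 2 fell and 7 were not called. Fos, Egr2 and Nr4a1 (0.72, adjusted p = 4.59e-08) were the called members with the smallest p, while Egr3 fell by 0.20 (adjusted p = 0.000559) and Fosl2 by 0.14 (adjusted p = 0.0339). The Fosl2 call ended without WT basal array 2, 3 or 4 or WT learning array 2, 3 or 4 (up to 0.0764). Activity-induced effector genes rose (17 up, 2 down and 11 not called of 30, median 0.30, adjusted p = 7.65e-05; adjusted p = 0.0536 with an estimated correlation). Among them were Tiparp (0.84), the phosphatase Dusp14 (0.50) and Gadd45g (0.62) up and Midn (−0.30) and Lmna (−0.22) down. Glucocorticoid-responsive genes rose (12 up, 1 down and 7 not called of 20, median 0.40, adjusted p = 3.69e-05; adjusted p = 0.0536 with an estimated correlation). Tsc22d3 rose by 0.92, Sgk1, a kinase, by 0.88 and the metallothionein Mt2 by 0.79, with Zbtb16 down (−0.22). Heat shock and protein folding genes rose (18 up, 2 down and 3 not called of 23, median 0.26, adjusted p = 0.00211; adjusted p = 0.624 with an estimated correlation). Among them were the chaperone Hsp90aa1 (0.25), Hspa4l (0.26) and Xbp1 (0.57). Calr (−0.22) and Dnajb5 (−0.15) fell, the latter not without WT basal array 1 or 2 (adjusted p up to 0.0713). FoxO target genes rose (19 up, 5 down and 6 not called of 30, median 0.26, adjusted p = 0.00246; adjusted p = 0.151 with an estimated correlation). Members included Gadd45a (0.78), the mitophagy receptor Bnip3 (0.84) and Sesn1 (0.57) up and Cited2 (−0.37), Pink1 (−0.25) and the ubiquitin ligase Fbxo32 (−0.37) down. Adjusted over the list alone, the counts up and down were the same, except 12 and 2 for glucocorticoid-responsive genes. The receptor genes with a median of 0.12 moved the same way.

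Many genes of synapses and of axon guidance fell in WT after learning, in lists that were called with the preset correlation and not with an estimated one. Of 47 genes of glutamate receptors and the postsynaptic density, 28 fell, 10 rose and 9 were not called (median −0.23, adjusted p = 6.71e-07; adjusted p = 0.0536 with an estimated correlation). Grik5, a kainate receptor subunit, fell by 0.71, Cacng8, an auxiliary AMPA receptor subunit, by 0.76, and Shank1 by 0.83, while Lrrtm2 (0.35), the scaffold Homer1 (0.42) and Dlg1 (0.25) rose. Of 46 genes of the presynaptic release machinery, 28 fell, 6 rose and 12 were not called (median −0.18, adjusted p = 7.43e-07; adjusted p = 0.0536 with an estimated correlation). Among them were Syn1, Ppfia3 (−0.66) and the endocytic GTPase Dnm1 (−0.40) down and Napb (0.30), Rab3c (0.26) and Snap25 (0.20) up. Of 57 axon guidance genes, 36 fell, 7 rose and 14 were not called (median −0.27, adjusted p = 6.79e-09; adjusted p = 0.0536 with an estimated correlation). They included the receptors Unc5a (−0.63) and Plxnb1 (−0.62) and Rgma (−0.66). Sema3e (0.24), Sema3a (0.52) and Unc5d (0.45), of which another probe differed in the opposite direction, rose. Potassium channel genes fell (24 down, 9 up and 18 not called of 51, median −0.12, adjusted p = 0.00336; adjusted p = 0.256 with an estimated correlation). Members were Kcna1 (−0.50), Kcnab2 (−0.62) and Kcnip2 (−0.58) down and Kcnv1 (0.44), Kcnmb4 (0.24) and Kcnip3 (0.30) up. CA1 pyramidal cell markers fell (6 down, 1 up and 1 not called of 8, median −0.27, adjusted p = 0.0104; adjusted p = 0.0694 with an estimated correlation). Mpped1 fell by 0.43, Pou3f1 by 0.51 and Fibcd1 by 0.51, with Lefty1 up (0.49). Insulin and PI3K signalling genes fell (18 down, 10 up and 6 not called of 34, median −0.19, adjusted p = 0.0257; adjusted p = 0.401 with an estimated correlation). Among them were Rptor (−0.58), a partner of mTOR, Pik3r2 (−0.57) and Gsk3a (−0.60) down and the GTPase Rheb (0.82), Sgk1 (0.88) and Insr (0.53, another probe in the opposite direction) up. The insulin list call ended without WT learning array 4 (adjusted p = 0.0518). Adjusted over the list alone, 7 presynaptic and 11 potassium channel genes rose and 37 axon guidance and 19 insulin signalling genes fell, and the other counts were the same. The receptor genes with a median of 0.12 moved the opposite way.

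Many metabolic and peptide genes rose in WT after learning. Of 72 oxidative phosphorylation genes, 51 rose, 5 fell and 16 were not called (median 0.27, adjusted p = 4.76e-09; adjusted p = 0.256 with an estimated correlation). Among them were Uqcrc2 (0.55), Atp5g3 (0.75) and Ndufs3 (0.45) up and Cox5b (−0.20), Uqcrh (−0.18) and Cox4i1 (−0.13) down. The Cox4i1 call ended without WT basal array 2 or 5 or WT learning array 1 or 5 (adjusted p up to 0.0567). Of 23 neuropeptide and granin genes, 12 rose, 2 fell and 9 were not called (median 0.20, adjusted p = 0.0264; adjusted p = 0.256 with an estimated correlation). Tac1, the substance P precursor, rose by 0.99, Vip by 0.80 and Scg5 by 0.52, while Vgf (−0.34) and Sst (−0.31) fell. The neuropeptide call ended without WT basal array 6 or WT learning array 4 (adjusted p up to 0.0553). Adjusted over the list alone, 55 oxidative phosphorylation genes rose and 8 fell, and the neuropeptide counts were the same. Beside them the receptor genes had a median of 0.12.

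The other 18 lists were not called in WT (adjusted p 0.0826 to 0.939), though most held genes that changed both ways. Interneuron markers had 6 up, 6 down and 6 not called, with Vip, Tac1 and Pvalb (0.38) up and Calb2 (−0.52), Slc32a1 (−0.23) and Maf (−0.31) down. GABA-A receptor subunits had 6 up, 1 down and 5 not called (Gabrg1 0.75, Gabra3 0.46, Gabrb1 0.35, Gabrd −0.20). The MEF2 family and reported targets had 5 up, 3 down and 6 not called, with Arc and Bdnf (0.64), a neurotrophin, up and Kcna1, Hdac5 (−0.52) and Mef2d (−0.78, another probe in the opposite direction) down. Clock genes had 7 up, 2 down and 8 not called, with Dbp (0.49), Nr1d2 (0.24) and Rorb (0.29) up and Nr1d1 and Cry2 (−0.22) down. Ribosomal proteins had 23 up, 8 down and 23 not called (adjusted p = 0.0826), with Rpl38 (0.67), Rps18 (0.49) and Rps20 (0.97) up and Rps15 (−0.48), Rps14 (−0.70) and Rps4x (−0.32) down. Dentate gyrus markers had 3 up, 4 down and 5 not called (Calb1 0.40, Tdo2 0.60, Pitpnm2 −0.48, Prox1 −0.41), and CA2 and CA3 markers 4 up, 3 down and 6 not called (Socs2 0.38, Pcp4 0.31, Rgs14 −0.38). Astrocyte markers had 4 up, 7 down and 3 not called (Gjb6 0.64, S100b 0.50, Sox9 −0.36), oligodendrocyte markers 4 up, 4 down and 6 not called (Ermn 0.53, Mag −0.40) and their precursors' markers 2 up, 4 down and 4 not called (Lhfpl3 0.47, Sox10 −0.62). Microglia markers had 5 up, 2 down and 8 not called (Ctss 0.62, C1qa 0.40, Csf1r −0.24) and endothelial and mural markers 4 up, 4 down and 7 not called (Itm2a 0.53, Pdgfrb −0.46, Cldn5 −0.46). Choroid plexus markers had 0 up, 2 down and 15 not called (median −0.20, adjusted p = 0.0826; Igfbp2 −0.47, and Kl −0.35, lost without WT basal array 1, 2 or 3 or WT learning array 4, adjusted p up to 0.0917). Meningeal and fibroblast markers had 4 up, 4 down and 6 not called (Lum 0.54, Igf2 −0.46), thalamic markers 3 up, 3 down and 8 not called (Slc17a6 0.60, Prkcd −0.29) and neocortical markers 2 up, 4 down and 8 not called (Lamp5 0.23, Bcl11b −0.25). Striatal markers had 0 up, 4 down and 8 not called (Ppp1r1b −0.40), and none of 5 blood markers was called (S100a8 −0.04, adjusted p = 0.607). Median and mean or test differed in sign for interneuron, neocortical and blood markers, with medians of 0.0078, 0.02 and 0.01 and tests that pointed down.

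Mutant mice showed nearly the same differences between learning and basal arrays as WT mice. Fos rose from 6.43 ± 0.21 to 8.16 ± 0.11 (1.73, SE 0.104, 3.31-fold, adjusted p = 6.59e-14), Egr2 by 1.03, Arc by 1.00 and Bdnf by 0.51, while Syn1 fell by 0.82 and Shank1 by 0.92. Of 8231 called genes (41.3%), 4508 rose and 3723 fell, 591 changed at least 1.5-fold and 25 at least 2-fold. Of the 8636 genes called in WT, 8543 (98.9%) had the same sign in the mutant, and 6913 were called in both genotypes, 6910 of them in the same direction, where independent calls would share 1810 in the same direction. Across genes these differences correlated at r = 0.921 (rho = 0.885), and at r = 0.940 and 0.964 without the dimmest 25% and 50% of genes. A difference in processing shared by both genotypes would also give such agreement and cannot be told apart from the task. The other largest rises were Sdhaf4 (1.38), Imp3 (1.31), Trim13 (1.31), Mrpl20 (1.29), Polr3e (1.26), Bex1 (1.16), Hint1 (1.14), the mitochondrial pyruvate carrier Mpc1 (1.13) and Bex4 (1.10). The largest falls were Ttr (−1.39, SE 0.471, adjusted p = 0.0176), which lost its call without mutant learning array 2 (adjusted p = 0.0636), Dtx3 (−1.31), Pltp (−1.23), Selenow (−1.05), Tmem88b (−1.02), Agpat1 (−1.01), Slitrk1 (−0.98), the Polycomb protein Pcgf1 (−0.94), Spry2, an inhibitor of receptor tyrosine kinase signalling (−0.93), and Shank1. Apart from Ttr and Mrpl20 (0.000114), the adjusted p of these largest rises and falls was at most 1.16e-07. Beside these genes, 263 of 1190 olfactory and vomeronasal receptor genes were called (22.1%), 262 of them higher, with a median of 0.11 that was 0.05 after a second quantile normalization and 0.13 with each array centred on its median. Under these scalings 3968 genes were called higher and 3946 lower, and 4778 and 3321. At a minimum of 1.2-fold the count was 4831.

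**Figure D3:**
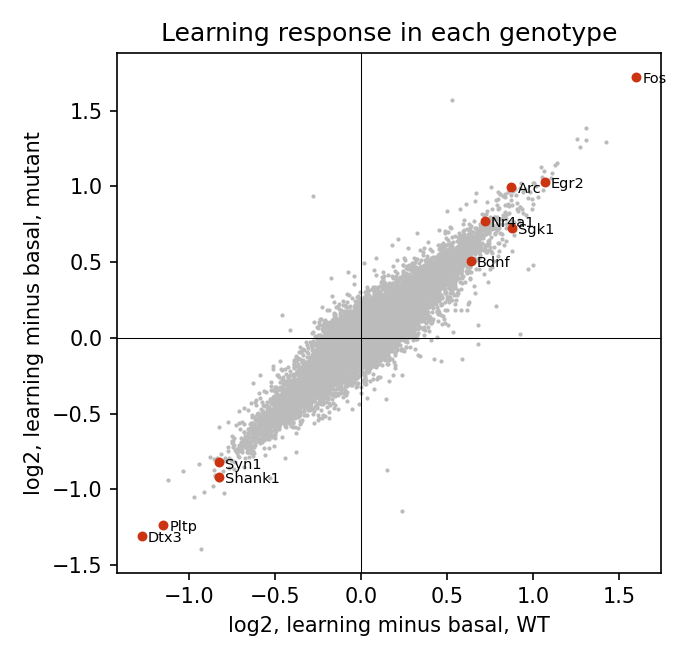
Learning minus basal (log2) of each gene in WT (x axis) and in the mutant (y axis). Each point is a gene, and labelled red points are genes named in the text, with Fos at 1.60 and 1.73 and Pltp at −1.15 and −1.23.

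In the mutant, the 13 lists called in WT were called in the same direction, and 2 more were. Immediate early genes (14 up, 1 down and 9 not called of 24, median 0.30, adjusted p = 2.86e-05; adjusted p = 0.0667 with an estimated correlation; Egr1 0.62, Nr4a1 0.77) rose. So did effector genes (18, 2 and 10 of 30, median 0.27, adjusted p = 6.58e-05; Tiparp 0.88) and glucocorticoid-responsive genes (14, 1 and 5 of 20, median 0.37, adjusted p = 2.59e-05; Ddit4 0.85, Sgk1 0.73), both at an adjusted p = 0.0537 with an estimated correlation. Heat shock genes rose too (15, 1 and 7 of 23, median 0.25, adjusted p = 0.00108; adjusted p = 0.532 with an estimated correlation; Hspa1a 0.78, Dnaja1 0.31). FoxO targets (17, 5 and 8 of 30, median 0.19, adjusted p = 0.00324; adjusted p = 0.158 with an estimated correlation; Bnip3 0.95, Bnip3l 0.38, Cited2 −0.46) rose. Neuropeptides (11, 2 and 10 of 23, median 0.17, adjusted p = 0.0474; adjusted p = 0.306 with an estimated correlation; Vip 0.86, Tac1 0.85) and oxidative phosphorylation genes (50, 5 and 17 of 72, median 0.26, adjusted p = 4.17e-09; adjusted p = 0.257 with an estimated correlation; Atp5g3 0.76, Sdhc −0.51) rose too. Genes of glutamate receptors and the postsynaptic density (5 up, 31 down and 11 not called of 47, median −0.23, adjusted p = 1.1e-08; Cacng8 −0.81, Grik5 −0.72), presynaptic genes (4, 28 and 14 of 46, median −0.18, adjusted p = 4.08e-08; Ppfia3 −0.71, Syp −0.42) and axon guidance genes (7, 35 and 15 of 57, median −0.28, adjusted p = 4.17e-09; Plxnb1 −0.71, Efna3 −0.62) fell. These 3 lists kept an adjusted p = 0.0468 with an estimated correlation. Potassium channels (7, 23 and 21 of 51, median −0.17, adjusted p = 7.57e-05; adjusted p = 0.12 with an estimated correlation; Kcna1 −0.57) fell as well. So did insulin signalling genes (9, 18 and 7 of 34, median −0.21, adjusted p = 0.00324; adjusted p = 0.24 with an estimated correlation; Rptor −0.63, Rheb 0.81, Rictor 0.33) and CA1 markers (1, 5 and 2 of 8, median −0.27, adjusted p = 0.00738; adjusted p = 0.0588 with an estimated correlation; Fibcd1 −0.52). The additional lists were ribosomal proteins, which rose (27 up, 10 down and 17 not called of 54, median 0.13, adjusted p = 0.0383; adjusted p = 0.705 with an estimated correlation; Rps21 0.87), and choroid plexus markers. The latter fell (0, 5 and 12 of 17, median −0.22, adjusted p = 0.0474; adjusted p = 0.705 with an estimated correlation; Igfbp2 −0.54). Adjusted over the list alone, called counts up and down were 15 and 1 for immediate early genes, 14 and 2 for glucocorticoid-responsive genes, 17 and 1 for heat shock genes, 51 and 5 for oxidative phosphorylation, 6 and 33 for glutamate receptors, 7 and 25 for potassium channels, 8 and 36 for axon guidance, 1 and 6 for CA1 markers and 0 and 1 for choroid plexus markers. For the other called lists they were the same as over all genes. The neuropeptide call ended without mutant basal array 4 or 6 or mutant learning array 2, 3 or 5 (adjusted p up to 0.0802), that of ribosomal proteins without mutant basal array 6 or mutant learning array 5 (up to 0.142), and that of choroid plexus markers without mutant basal array 1, 3, 4 or 6 or mutant learning array 1, 2, 3 or 5 (up to 0.109). The other 16 lists were not called (adjusted p 0.12 to 0.942); interneuron markers had a median of −0.05 and a mean of 0.0042, and the MEF2 list a median of 0.03 with a test that pointed down. The receptor genes moved with the lists that rose.

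No gene passed the test for a response to learning that differed between genotypes: limma called 0 genes in the interaction, with 510 at an unadjusted p under 0.05 where chance gives 996.9. The genes with the smallest p are given as values, all with an adjusted p that rounds to 1. Among negative ones these were Spry2 at −0.40 (SE 0.084, unadjusted p = 5.03e-05), the checkpoint kinase Chek1 at −0.43 (unadjusted p = 0.000221), Hmgb2 at −0.39 (unadjusted p = 0.000492), the gap junction gene Gjd2 at −0.35 and Cldn12 at −0.31. Among positive ones they were the proton pump subunit Atp6v1c2 at 0.51 (unadjusted p = 0.000398), Mycl at 0.32, the non-coding Gas5 at 1.21 (SE 0.362), Crocc at 0.34 and Sry at 0.33. The interaction was 0.10 for Foxo6, −0.18 for Foxo1 (unadjusted p = 0.025), −0.10 for Foxo3 and 0.04 for Foxo4. Of 31 lists, endothelial and mural cell markers had a lower response in the mutant (12 of 15 lower, median −0.13, adjusted p = 0.00663; adjusted p = 0.907 with an estimated correlation). None of their members was called over all genes or when adjusted over the list alone (Cldn5, of the tight junction, −0.19, and the receptor Flt1 −0.14). This list lost its call without WT learning array 2 or mutant learning array 1 (adjusted p up to 0.121), which left 0 lists. The number of called lists was 2 without WT basal array 4, mutant basal array 4, 5 or 6 or mutant learning array 2 or 6, 3 without WT basal array 6 or mutant learning array 5, and 4 without WT basal array 3 or WT learning array 1. The other 30 lists were not called (adjusted p 0.0563 to 0.867). Median and mean differed in sign for effector genes, heat shock genes and neocortical markers, and the test of striatal markers pointed up with a median of −0.02. In the simulated data, with genes drawn independently, differences of 0.5 on the log2 scale in the interaction were found for 73.1% of genes. There, 67 genes were changed by that amount at once, beside genes changed by 0.25 and 1. The adjustment is stricter where fewer genes change, so 73.1% overstates what could be found with 0 genes called. Atp6v1c2, at 0.51, was not called here.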

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

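The tests of probe mismatch, of receptor genes and of interneuron markers against other cell types were chosen after the results were seen. A single array lay far from the other 5 of its group in 62 of 856 groups of values of genes named in the text (214 genes), where chance picks about 1 in 20, or 42.8. Values are log2 levels. Among WT basal arrays, array 1 lay below in Bex4 5.86 and Trpc6 8.26. Array 2 lay below in Homer2 9.14, Lrrtm2 9.91 and Rptor 8.88 and above in Itm2a 9.81. Array 4 lay below in Hyi 6.88 and above in Cap1 11.56, Nr4a1 9.80 and Slitrk1 9.92. Array 5 lay above in Kcnip3 9.29 and Prkcd 8.02. Array 6 lay below in Bnip3l 10.90, Hint1 8.92, Med8 7.10, Mpc1 8.87, Napb 10.83, Penk 8.70, Pou3f1 8.72, Rpl38 10.70, Shank1 9.86 and Snap25 12.01 and above in Gas5 10.50 and Kcnv1 9.25. Among mutant basal arrays, array 2 lay below in Stxbp6 9.32 and above in Dtx3 10.09. Array 4 lay below in Cry2 9.48 and Slc17a6 8.84 and above in Ctss 9.77. Array 6 lay below in Dnaja1 10.94, Klhl2 10.67, Sgk1 8.47 and Trpc6 8.08 and above in Foxo6 6.59 and Txnip 7.85. Among WT learning arrays, array 1 lay below in Gad2 10.03, Gas5 8.57 and Pink1 10.07. Array 2 lay below in Vgf 8.09 and above in Dnaja1 11.58. Array 4 lay above in Cox4i1 10.69. Array 5 lay below in Imp3 9.08, Maf 7.12 and Ndufs5 9.21 and above in Chek1 5.87 and Mrpl20 8.85. Among mutant learning arrays, array 1 lay below in Ermn 9.79 and Sdhc 9.79 and above in S100a8 5.26. Array 2 lay below in Csf1r 8.56 and Igfbp2 7.39. Array 3 lay below in Foxo1 8.37, Gsk3a 9.49, Ndufs3 10.69 and Tdo2 6.73 and above in Hcrtr1 6.73. Array 5 lay above in Hsp90aa1 13.02, Rab3c 11.35 and Trim8 8.28. Array 6 lay above in Kl 7.44, Rps21 10.66 and Vgll3 6.40. Among these, Foxo6 in mutant basal array 6 (6.59) lay above the other mutant basal arrays (6.18 to 6.32). WT basal array 6 held 12 of the values, the most of any array.

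The response of endothelial and mural cell markers to learning was called between genotypes (median −0.13, adjusted p = 0.00663; adjusted p = 0.907 with an estimated correlation; 12 of 15 markers lower). The call ended without WT learning array 2 or mutant learning array 1 (adjusted p up to 0.121). The mean of the markers lay above the WT mean in 5 of 6 mutant arrays at basal and below it in 4 of 6 after learning. Of the 13722 probes without a single gene, 13 were called between genotypes at basal, 15 after learning, 27 over both states, 3022 for learning in WT and 2969 in the mutant.

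Other splits of the arrays into groups of the same sizes, 100 per comparison with the real one included, showed how often other groupings call as many genes. At basal 1 split, the real one, gave as many genes (20, highest other 5). After learning 2 did (15, highest other 18), and over both states 1 (78, highest other 2). For learning in WT it was 1 (8636, highest other 4562) and in the mutant 1 (8231, highest other 5374). Such counts were thus rare among the 100 splits, which does not exclude chance. After learning, 1 other split called more genes than the real one. For the learning comparisons, the real split also parts the basal from the learning arrays and cannot tell the task from processing. For the interaction the real count was 0, which all 100 splits reach whatever the data, so the splits say nothing about chance there. The highest other count, 146 with genotypes mixed within states, points to a structure of the samples, whose source was not tested.

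Genes called between genotypes lay near Foxo6, with an odds ratio of 26.2 within 20 Mb. This is what sequence of the other parent strain carried around the mutant allele needs, on the mixed background of these mice, and it may account for the calls there without any act of FoxO6. Mismatched bases under the probes lower a signal. If only the mutants carried them, they would not give the 16 called genes near Foxo6 that were higher in the mutant. The labels used here give only a mixed background and not the strain that WT mice carry near Foxo6, so this was not settled. For the 14 lower ones, mismatched probes and lower RNA cannot be told apart, because probe sequences were not used. For genes elsewhere, such as Grp, Crym and Fibcd1, loss of FoxO6 stays open. So do strain sequence at other places on the mixed background and differently cut pieces. None of these was tested further for these genes.

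Many genes (8636 in WT, 8231 in the mutant) differed between basal and learning arrays. Receptor genes of the olfactory and vomeronasal organs, at low levels in the hippocampus arrays, were called in 22.1% of cases in the mutant and 26.8% in WT, nearly all higher, as a difference between the sets of arrays other than the task might give. A shift set by expression level and gene length as the whole cause was compared with random lists matched on both. The median of immediate early genes lay at percentile 99.98 of these lists in the genotype nearer the middle, which argues against it. With an estimated correlation that list was not called (adjusted p = 0.117 in WT, 0.0667 in the mutant). The median of glutamate receptor and postsynaptic density genes lay at percentile 0, which argues against such a shift there (adjusted p = 0.0536 in WT and 0.0468 in the mutant with an estimated correlation). The random lists do not keep the correlation between genes of a list. Both percentiles may therefore overstate how far these lists stand out, and such a shift was not excluded. Batch and task share the same arrays and cannot be told apart. The task, handling and the arena stay open for these lists. Single housing is given only for the basal mice and was not separated from these.

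Dentate gyrus markers were lower in the mutant over both states, with their mean below the WT mean in 6 of 6 mutant arrays of each state. The arrays of the genotypes overlapped. The mean of the markers was 8.04 to 8.19 in the mutant against 8.16 to 8.40 in WT at basal. After learning it was 8.04 to 8.13 against 8.05 to 8.24. Choroid plexus carried along with the pieces is argued against: with its score as a covariate, chosen after seeing the data, the median was −0.13 (adjusted p = 2.56e-09; adjusted p = 0.0269 with an estimated correlation). Without the covariate the adjusted p with an estimated correlation was 0.0598 at basal, 0.851 after learning and 0.0883 over both states. Interneuron markers rose beyond those of CA1, astrocytes, oligodendrocytes, their precursors and microglia by 0.0907 (95% interval 0.0436 to 0.138), and by 0.0823 (0.0361 to 0.128) with CA2 and CA3 markers among them, which a loss of dentate cells that raised these types alike does not give. This test was chosen after the rise of interneuron markers had been seen, and the intervals do not allow for that choice. Beyond CA2 and CA3 markers alone the rise was 0.0401 (−0.0208 to 0.101), an interval that holds 0, and the interneuron list lost its call with an estimated correlation (adjusted p = 0.0883). Choroid plexus and neocortical markers were also called higher, but not with an estimated correlation (adjusted p = 0.477 and 0.443), and the neocortical call held in 15 of 24 runs without an array. A differently cut piece with less dentate tissue could lower the dentate markers and cannot be told apart from lower RNA per cell without FoxO6: the markers' residuals correlated at 0.198, at percentile 96.6 of random lists, whose median was 0.0454 and whose 95% range ended at 0.212.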

How the results depend on the processing

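Tests chosen after the data had been seen were those without the chromosome of Foxo6, with the choroid plexus score as a covariate, without the least typical array of each group, and of lists without genes near Foxo6. Values were recomputed under alternatives chosen before the data were examined. Of these, 17868 of named genes and 3703 of lists kept their side of the threshold, and called ones their direction. Of the others, 598 and 127 lost the call and 23 and 74 gained it. A further 4 uncalled ones of genes moved by more than their SE, and 2 of lists changed direction with a call. Under the added alternatives 1113 and 529 kept their side in the same sense, 50 and 8 lost the call and 3 and 14 gained it. There, 16 of genes moved and 7 of lists changed direction with a call. Values not called on either side also changed sign, in 18 cases for genes and 231 for lists. These sign changes are not counted above as changes of direction.

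Counts of genes between genotypes (20 at basal, 15 after learning, 78 over both states) moved by over 1.5 times in the following cases; unless a reason is given, the cause was not tested. With each array centred on its median they were 10, 9 and 44, and without a trend in eBayes 7 and 9 for the single states. Array weights gave 51 at basal and 9 after learning, and a model of only the arrays of the groups compared, which has fewer arrays, 11 and 7; that model has no value for the interaction and both states. Every probe, named or not, gave 28 after learning, over more tests. The first residual component as a covariate, which lowers the residual spread by construction, gave 58 after learning and 173 over both states. The stricter adjusted p under 0.01 gave 5, 7 and 33, and a minimum of 1.2-fold gave 25 over both states, 4979 for learning in WT and 4831 in the mutant. Without the genes within 20 Mb of Foxo6 the counts were 6, 6 and 36, and without its chromosome 6, 6 and 34. Since 12, 8 and 47 called genes lay outside the window, the counts fell by more than the removed genes, with the new fit and adjustment over the genes left. With the choroid plexus score as a covariate 44 genes and 5 lists were called over both states.

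With the correlation estimated per list, 0 lists were called at basal, 0 after learning, 0 over both states, 0 for the interaction, 0 for learning in WT and 3 in the mutant. Without the least typical array of each group, 6 lists were called after learning and 6 for the interaction. In these runs the tests of oxidative phosphorylation genes pointed the other way, with medians of 0.0065 at basal and 0.0438 for the interaction, as did heat shock genes, with −0.0669 after learning and −0.0940 for the interaction. With the choroid plexus score as a covariate, choroid plexus markers had medians of −0.0325 at basal, 0.0016 after learning and −0.0104 over both states, since the score is made from them. Without the dimmest 25% and 50% of genes, the learning responses of the genotypes correlated at 0.940 and 0.964.

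Leaving out each array in turn gave 6 to 26 genes at basal (6 without mutant basal array 2, 9 without WT basal array 2 or mutant basal array 6, 10 without WT basal array 3 or 5, 11 without WT basal array 4 and 12 without mutant basal array 3), 8 to 16 after learning (8 without WT learning array 2 or mutant learning array 1 and 9 without mutant learning array 3), 55 to 98 over both states, 8058 to 8612 for learning in WT, 7707 to 8244 in the mutant and 0 to 0 for the interaction. Lists ranged from 4 to 14, 0 to 6, 5 to 11, 11 to 15, 12 to 15 and 0 to 4 in the same order. At basal 4 were called without mutant basal array 1 or 2 and 14 without WT basal array 3, and after learning 0 without mutant learning array 4 and 6 without WT learning array 4. Over both states 5 were called without WT learning array 1 or mutant learning array 5 or 6, and for the interaction 0 without WT learning array 2 or mutant learning array 1 and 4 without WT basal array 3 or WT learning array 1. The Foxo6 difference ranged from −0.79 to −0.67 at basal and from −0.68 to −0.58 after learning. Oxidative phosphorylation genes at basal ranged from a median of 0.00022 without WT basal array 6, where the test pointed down, to 0.0485 without WT basal array 2. Ribosomal proteins at basal ranged from −0.0273 without WT basal array 6 to 0.0437 without WT basal array 1.

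With the replicate number as a block the counts were 14, 11, 62, 8634, 8261 and 0. The numbers do not pair the arrays: residuals of arrays with the same number correlated at −0.30 to 0.45, and an array's best match had its own number in at most 3 of 6 cases. Signal over background was not used here, so what it limits was not tested.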

Other observations

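The tests of this part were chosen after the data had been seen, that of the median of cell division genes before its own result was known. Gene families outside the lists moved after learning. Of 77 mitochondrial ribosomal protein genes, 52 rose and 4 fell in WT (median 0.24, adjusted p = 4.47e-09; adjusted p = 0.378 with an estimated correlation), and 49 rose and 3 fell in the mutant (0.26, adjusted p = 1.89e-09; adjusted p = 0.288 with an estimated correlation). Of 40 proteasome subunit genes, 23 rose and 3 fell in WT (0.19, adjusted p = 0.000138; 0.378 with an estimated correlation) and 24 rose and 4 fell in the mutant (0.18, adjusted p = 5.63e-05; 0.288 with an estimated correlation). Of 44 collagen genes, 0 rose and 17 fell in WT (−0.18, adjusted p = 6.17e-05; 0.784 with an estimated correlation) and 0 rose and 12 fell in the mutant (−0.14, adjusted p = 0.000547; 0.863 with an estimated correlation). Of 317 zinc finger protein genes, 142 rose and 49 fell in WT (0.15, adjusted p = 0.00442; 0.699 with an estimated correlation) and 127 rose and 49 fell in the mutant (0.14, adjusted p = 0.0084; 0.803 with an estimated correlation). These zinc finger medians lie near those of the olfactory and vomeronasal receptor genes (0.12 in WT, 0.11 in the mutant), of which 22.1% were called in the mutant, so a difference between the sets of arrays other than the task might give them. After a second quantile normalization they were 0.14 in both genotypes, against 0.07 and 0.05 for the receptor genes, and with each array centred on its median 0.18 and 0.15, against 0.16 and 0.13. The directions of these 4 families held under both other scalings.

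Between genotypes, zinc finger protein genes were lower in the mutant at basal (median −0.02, adjusted p = 0.00519; 0.810 with an estimated correlation), after learning (−0.04, adjusted p = 0.00328; 0.578 with an estimated correlation) and over both states (−0.03, adjusted p = 8.01e-05; 0.326 with an estimated correlation), with 0 called by limma. Aminoacyl-tRNA synthetase genes (30 members) were lower after learning (−0.05, adjusted p = 0.00461; 0.578 with an estimated correlation) and over both states (−0.03, adjusted p = 0.00221; 0.326 with an estimated correlation), with 0 called. In camera, genes with integrin names (31 members) were higher at basal (0.04, adjusted p = 0.0317, and 0.317 with an estimated correlation). They were also higher over both states (0.03, adjusted p = 0.0389, and 0.326 with an estimated correlation). In each case limma called 2, Itga4 and Itgbl1, of which Itgbl1 is integrin-like. Since this family was chosen after the data had been seen, its test is not independent of these 2 calls.

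Chek1, Hmgb2 and Rrm2, the last named after its values were seen, act in dividing cells and stood among the lower responses of the mutant, though limma called 0 genes in the interaction. A hypothesis was that the mutant might hold fewer dividing cells after learning. The median interaction of 32 other cell division genes was 0.0012 on the log2 scale, 16 of them above and 16 below 0. The lowest of them was at −0.21, against −0.43, −0.39 and −0.47 for the 3 genes. Of the 32, 23 had a mean level above that of 95% of the olfactory and vomeronasal receptor genes, and their median was 0.0055. As a set, the other genes showed no common fall. The 3 genes were picked for their low values, which may overstate their change, and limma called none of them. How far fewer dividing cells would lower the other genes is not known, so fewer dividing cells were not excluded.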
